A study of Oncorhynchus mykiss with 32 samples.

How the data were processed

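Liver RNA of juvenile rainbow trout exposed to 1 of 4 hydrocarbon products for 96 h was hybridised to cDNA arrays together with RNA of control fish, per the labels with the control in channel 1 and the exposed fish in channel 2 on every array. The labels give 3 biological replicates per product, each on 1 to 4 technical arrays, and say that exposed and control samples were paired at random. They do not say whether products shared control fish, and no array has the dyes exchanged. The 32 deposited scanner tables hold 17328 spots in 48 blocks, of which 1278 were control or empty spots and 77 were chimeric clones, both left out of the results.

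Spot and local background values were taken as pixel intensity on a linear scale, per the file headers. The share of saturated pixels is a percent, per the file headers, and reached over 50 percent of the pixels on at most 6 spots of an array; such spots were kept. The spot flag is a score whose codes the deposited tables leave unexplained, and spots of any code but 3, which was taken from the spot sizes and signals as that of located spots, were left out. The series table was read as log2 of channel 2 over channel 1, normalized within each array by the authors by a method not given in the sources used here. Its direction and scale were taken from its correlation with the scanner values, which lay between 0.77 and 0.92 per array, and its array medians lay between -0.045 and 0.082. The scanner software and its version are not given in the sources used here.

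Intensities were background corrected by normexp with an offset of 50 and normalized by loess over each whole array with a span of 0.3, with limma 3.58.1 in R 4.3.3; the data.table package, version 1.17.8, read the tables. A clone was used if it was above background by 2 background SD in either channel on at least 0.5 of the arrays of a product. Of 15940 clones, 13864 remained, 10269 of them with a gene name. Gene names are those the array's own annotation gives, often from another species by sequence likeness; the clones' sequence identifiers were not matched to a genome, so no positions are given. Closely related genes may share a clone's signal. The median spot intensity of an array lay between 282 and 3815 in channel 1, and 3 arrays had under 70% of spots located. These were array 1 of heavy fuel oil replicates 2 and 3 (66.9% and 67.2%) and array 1 of kerosene replicate 2 (63.3%).

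Technical arrays were averaged per biological replicate, and limma fitted 1 mean per product on the 12 biological replicates, with 1 prior variance for all clones. Each product, the mean of the 4, the 6 differences between products and an F test among products were tested, with Benjamini-Hochberg adjustment per comparison and a limit of 0.05; each test is two-sided. A comparison used the clones with a value in every replicate of its products. The ratio against 0 leaves any dye effect in place. The lowest correlation of log2 ratios between any pair of arrays was -0.37 over all clones valued on both arrays and -0.42 over the 8899 used clones valued on every array, the latter between different products. Over these 8899 clones the lowest between technical arrays of 1 biological replicate was -0.21 (kerosene). Between biological replicates of 1 product it was -0.23 (heavy fuel oil). The direction was kept because the labels state the dyes. For a clone above background on no array of a channel, the fold is given as a bound from the channel levels after loess and Aquantile, which is open to dye bias.

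Lists of pathway genes and cell type markers, 35 in all, were written before the data were examined, as patterns on clone names. They were tested with limma camera (preset correlation 0.01) on the clones with values in all 12 replicates, for the 4 products and their mean, with the p adjusted over the lists of a comparison. Each clone counted singly, so a gene with several clones counted several times. Every camera call was repeated with an estimated correlation. None of the calls held with it in any of these comparisons. Limma fry, which tests a list against 0 rather than against the other clones, was set beforehand to be given beside camera. By its adjusted p, 12 of the 35 lists passed with crude oil, 2 with heavy fuel oil and 1 with kerosene. With gas oil 17 passed, and for the mean 14. Exclusions of names that a pattern caught by mistake were chosen after the data were seen, from the names alone, and serve only as an alternative. The named clones follow a rule set before the data were examined: per product, among named clones that passed with the same sign in all 3 replicates, the 10 largest rises and 10 largest falls with 1 clone per name, the 2 smallest p of each list, and every cytochrome P450 1A clone; per pair, the 5 smallest p that passed; for the mean and the F test, the 10 smallest p. Where fewer passed, the smallest p are given as values. The stomach clones as a set were chosen after their values were seen.

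The limma fit was tested on simulated log2 ratios of the biological replicates with 50 changed clones per size, at log2 changes of 0.5, 1, 2 and 3. The values were independent normal draws per clone, with the spread and missing values of the data. They held no dye effect and no correlation between clones, and background correction, loess and averaging of arrays were not run on them. The shares below therefore do not give the error rate of the real counts. In the simulation of crude oil against control, over 13580 clones, 68%, 96%, 100% and 100% were recovered, with 10 of 192 calls wrong. In that of crude oil minus heavy fuel oil, over 12995 clones, 42%, 90%, 100% and 100% were recovered, and in that of differences among products, over 12327 clones, 38%, 86%, 100% and 100%.

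Alternatives set before the data were examined were no background subtraction, print-tip loess, no filter on dim clones, the replicate number as a block, all arrays with duplicateCorrelation, the authors' log2 values, all flag codes kept, an intensity trend in the prior variance, and each biological replicate left out in turn. Chosen after the data were seen were a test against the mean of the other 3 products, the arrays with under 70% of spots located left out, the gas oil arrays with stomach transcripts in the control channel left out, the lists without misfit names, and the pre-ranked form of camera. With duplicateCorrelation, the lists were tested by the pre-ranked form. The correlation it took between technical arrays of a biological replicate was 0.13, so they entered that fit almost as separate samples. The software's own normalized columns in the scanner tables were not used here. The scanner tables and labels give no scan date or slide, so no such batch was tested.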

Results

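Transcripts in the liver of juvenile rainbow trout were measured on 32 arrays of cDNA clones, each of which set the RNA of a fish exposed for 96 h to 1 of 4 hydrocarbon products against that of a control fish of the same time. The fish were held in the WAF of crude oil, heavy fuel oil or kerosene at 2 mg/L, or of gas oil at 1 mg/L, so the gas oil groups differed in dose as well as in product. Each product had 3 biological replicates, on 6 arrays for crude oil, 9 for heavy fuel oil, 8 for kerosene and 9 for gas oil. The arrays carried 15940 different clones, of which 13864 were above background often enough to be used. These held 5250 different gene names, and many genes were on the array as several clones. The median spot intensity per array ran from 282 to 3815 in the control channel and from 266 to 3217.5 in the exposed channel, and the number of arrays limits the precision. The scanner located between 63.3% and 87.3% of the spots of an array. Values below are log2 ratios of exposed over control liver as mean ± SD over the 3 biological replicates, unless another error is named.

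The comparison of crude oil with control asked which transcripts the exposed liver held more or less of. The clones that rose most included 2 of cytochrome P450 1A, the oxidase that the aryl hydrocarbon receptor switches on, and some of enzymes that conjugate xenobiotics. A cytochrome P450 1A3 clone had a log2 ratio of 4.02 ± 0.14 (SD, n = 3; limma adjusted p = 5.6e-04). Its control signal was above background on none of the 6 arrays (0 of 6), and its exposed signal on 4, so that the rise was at least 5.78-fold. The cytochrome P450IA1 clone rose by 2.04 ± 0.23 (limma adjusted p = 8.9e-05), while the other P450 1A3 clones gave 0.53 ± 0.11 (limma adjusted p = 0.020) and 0.13 ± 0.076 (limma adjusted p = 0.18, not passing). Glutathione S-transferase P, which couples glutathione to reactive compounds, rose by 2.84 ± 0.54 (limma adjusted p = 6.4e-05), glutathione transferase omega-1 by 1.76 ± 0.44, microsomal glutathione S-transferase 3 by 1.64 ± 1.12 and sulfotransferase 6B1 by 1.43 ± 0.21. Thioredoxin, which reduces protein disulfides, rose by 1.74 ± 0.62, and GDP-L-fucose synthetase, which makes the sugar donor for fucosylation, by 1.87 ± 0.47. Metallothionein B, a protein that binds metal ions, rose by 1.57 ± 0.50 in 1 clone (limma adjusted p = 5.6e-04). Among the clones that fell most were those of secreted plasma proteins. Serum amyloid P-component, a pentraxin, changed by -2.17 ± 0.62 (limma adjusted p = 5.6e-04), haptoglobin, which binds free hemoglobin, by -1.86 ± 0.61 (limma adjusted p = 0.031), apolipoprotein CII by -1.53 ± 0.29, complement factor H by -1.43 ± 0.48, complement factor B by -1.34 ± 0.35 and coagulation factor XIII B by -1.14 ± 0.57. Protein disulfide-isomerase, which folds secreted proteins, fell as well, at -1.17 ± 0.20, and so did secreted phosphoprotein 24, at -1.17 ± 0.084.

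Taken by the lists fixed beforehand, the clones of plasma proteins were lower with crude oil as groups. Many of these clones share a gene name. The 44 coagulation clones had 17 names, the 31 acute phase clones 14, the 55 complement clones 22 and the 57 apolipoprotein clones 14. The estimated correlation between the clones was 0.19, 0.038, 0.085 and 0.15 in this order, above the preset 0.01. Coagulation and fibrinolysis had 1 of 44 clones higher, 12 lower and 31 not passing, or 2 higher and 16 lower adjusted over the list alone. The coagulation list had limma camera adjusted p = 1.1e-05, and adjusted p = 0.25 with an estimated correlation. Acute phase proteins had 0 of 31 clones higher, 8 lower and 23 not passing, or 1 higher and 12 lower adjusted over the list alone. The acute phase list had limma camera adjusted p = 8.2e-05, and adjusted p = 0.21 with an estimated correlation. Complement had 2 of 55 clones higher, 11 lower and 42 not passing, or 3 higher and 17 lower adjusted over the list alone. The complement list had limma camera adjusted p = 2.4e-04, and adjusted p = 0.23 with an estimated correlation. Apolipoproteins, the carriers of lipid in plasma, had 1 of 57 clones higher, 13 lower and 43 not passing, or 2 higher and 15 lower adjusted over the list alone. The apolipoprotein list had limma camera adjusted p = 0.0031, and adjusted p = 0.45 with an estimated correlation. Not every clone of these lists that passed was lower. A clone of apolipoprotein A-IV rose by 0.55 ± 0.067, while 1 of the 5 clones of that name fell, and the plasminogen activator inhibitor 1 RNA-binding protein, an RNA-binding protein that the coagulation list caught by its name, rose by 0.63 ± 0.26. The metallothionein list was higher, with 3 of 7 clones higher, 0 lower and 4 not passing, or 3 higher and 0 lower adjusted over the list alone. The metallothionein list had limma camera adjusted p = 1.9e-04, and adjusted p = 0.23 with an estimated correlation. Its 7 clones had 4 gene names, and the estimated correlation was 0.56. Skeletal muscle markers were lower, with 1 of 146 clones higher, 11 lower and 134 not passing, or 1 higher and 11 lower adjusted over the list alone, creatine kinase M among them at -0.61 ± 0.085. The skeletal muscle list had limma camera adjusted p = 0.019, and adjusted p = 0.21 with an estimated correlation. The aryl hydrocarbon receptor list, with 3 of 17 clones higher, 0 lower and 14 not passing, or 3 higher and 0 lower adjusted over the list alone, did not pass as a group (limma camera adjusted p = 0.066, and adjusted p = 0.21 with an estimated correlation). That test covered 16 of them and left out the P450 1A3 clone that rose most, which lacked a value with kerosene. With all 17, the pre-ranked limma camera, chosen after the data were seen, gave adjusted p = 0.016, which passes. It also gave 0.043 for ribosomal proteins, lower, where the test before had limma camera adjusted p = 0.054, and adjusted p = 0.66 with an estimated correlation. The list of conjugation enzymes, with 7 of 48 clones higher, 2 lower and 39 not passing, or 7 higher and 2 lower adjusted over the list alone, passed by neither (limma camera adjusted p = 0.096, and adjusted p = 0.21 with an estimated correlation; pre-ranked 0.10). By limma fry, which tests a list against 0, the aryl hydrocarbon receptor list (adjusted p = 3.7e-04) and the conjugation enzymes (0.0011) passed. These were among 12 of the 35 lists that passed by it. So did coagulation (limma fry adjusted p = 0.012), complement (0.0042), acute phase (9.9e-04), metallothionein (0.0016), glycolysis and gluconeogenesis (0.0011) and cell cycle and DNA repair (0.0011). The apolipoprotein list did not pass by limma fry (adjusted p = 0.078). Of all 13580 clones tested, 1907 passed at a limma adjusted p under 0.05, 1052 higher and 855 lower, and 47 of these changed by more than 1 log2 unit. The count fell to 153, 616 or 100 without biological replicate 1, 2 or 3, and was 1165 with the replicate number as a block and 1139 from the authors' log2 values. All arrays had the control in the same dye, and against the mean of the other 3 products, where a shared dye effect cancels, the count was 80, with 14 higher and 66 lower.

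**Figure D1:**
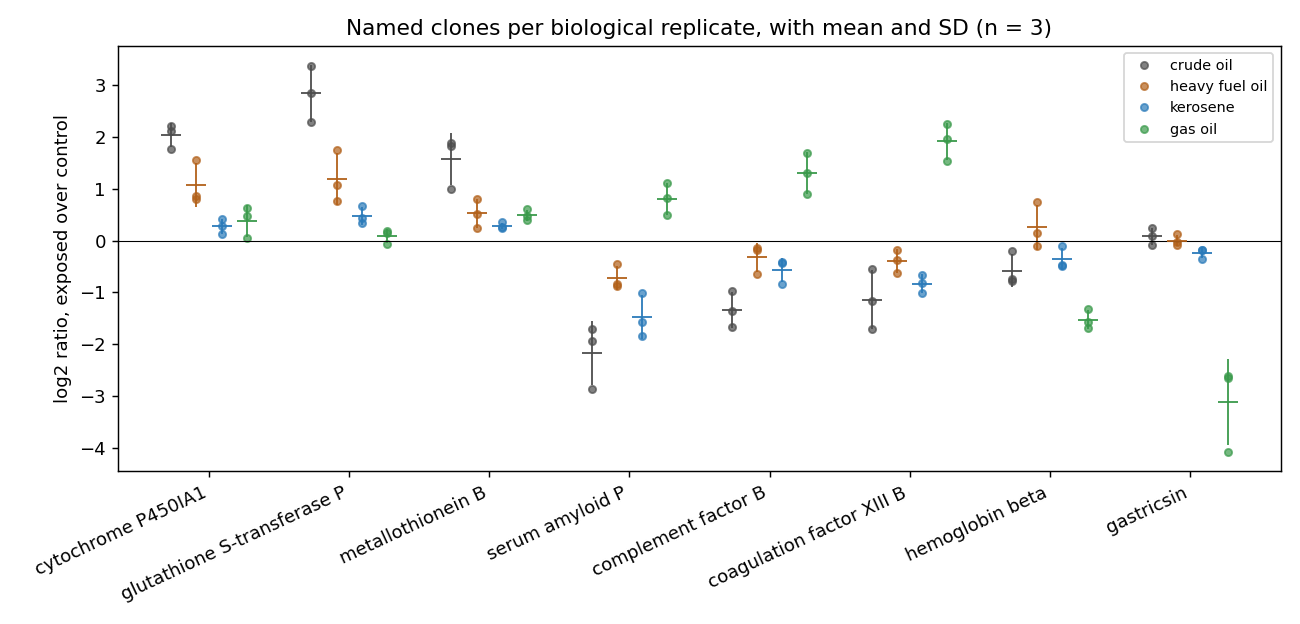
The log2 ratio of exposed over control liver (vertical axis) for 8 clones (horizontal axis), with a point for each of the 3 biological replicates of each product and the mean with its SD. Cytochrome P450IA1 stands at 2.04 ± 0.23 with crude oil and 0.27 ± 0.14 with kerosene, and coagulation factor XIII B at -1.14 ± 0.57 with crude oil and 1.92 ± 0.36 with gas oil.

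The same question was put for heavy fuel oil at 2 mg/L. The cytochrome P450 1A clones that were highest with crude oil rose here too: P450IA1 by 1.07 ± 0.43 (SD, n = 3; limma adjusted p = 0.014) and the P450 1A3 clone by 1.83 ± 0.55 (limma adjusted p = 0.030), whereas the other P450 1A3 clones stood at -0.060 ± 0.055 and -0.014 ± 0.33 and did not pass. Serum albumin 2, the main carrier protein of plasma, rose by 1.65 ± 0.98 (limma adjusted p = 0.024), lipocalin by 1.63 ± 0.56, and hemopexin, which binds heme, by 1.16 ± 0.47. The organic anion transporter 1B2, an uptake carrier, rose by 1.28 ± 0.86 and glutathione S-transferase P by 1.19 ± 0.50. Cytoplasmic actin 1, a filament protein, rose by 1.21 ± 0.14 (limma adjusted p = 0.0036), the heat shock 70 kDa cognate 4, a chaperone, by 1.13 ± 0.29 and apolipoprotein A-I by 1.12 ± 0.32. Of the clones that changed by more than 1 log2 unit, 27 rose and 4 fell. The falls included the copper chaperone ATOX1 at -1.78 ± 0.52 (limma adjusted p = 0.028), histidyl-tRNA synthetase, which loads histidine on its tRNA, at -1.66 ± 0.90 (limma adjusted p = 0.033) and the collagen alpha-1(I) chain at -1.08 ± 0.49.

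As groups, 6 of the 35 lists were higher with heavy fuel oil and none was lower. Array 1 of replicates 2 and 3 had under 70% of spots located. Over all products, the list calls by camera fell from 30 to 19 without the arrays under that limit. Ribosomal proteins had 15 of 499 clones higher, 1 lower and 483 not passing, or 35 higher and 3 lower adjusted over the list alone, with the acidic protein P0 at 1.07 ± 0.39. The ribosomal protein list had limma camera adjusted p = 9.0e-04, and adjusted p = 0.72 with an estimated correlation. Apolipoproteins had 4 of 57 clones higher, 0 lower and 53 not passing, or 16 higher and 3 lower adjusted over the list alone. The apolipoprotein list had limma camera adjusted p = 0.0060, and adjusted p = 0.72 with an estimated correlation. Coagulation and fibrinolysis had 4 of 43 clones higher, 0 lower and 39 not passing, or 8 higher and 0 lower adjusted over the list alone, with kininogen-1 at 1.06 ± 0.59. The coagulation list had limma camera adjusted p = 0.036, and adjusted p = 0.72 with an estimated correlation. Conjugation enzymes had 2 of 45 clones higher, 0 lower and 43 not passing, or 7 higher and 1 lower adjusted over the list alone, with a UDP-glucuronosyltransferase at 0.66 ± 0.24. The conjugation enzyme list had limma camera adjusted p = 0.036, and adjusted p = 0.39 with an estimated correlation. Iron handling had 2 of 69 clones higher, 0 lower and 67 not passing, or 3 higher and 2 lower adjusted over the list alone. The iron handling list had limma camera adjusted p = 0.036, and adjusted p = 0.72 with an estimated correlation. Erythrocyte markers had 1 of 75 clones higher, 0 lower and 74 not passing, or 1 higher and 0 lower adjusted over the list alone. The erythrocyte list had limma camera adjusted p = 0.036, and adjusted p = 0.72 with an estimated correlation. Its median log2 ratio was 0.38 on array 1 of replicate 2, but between -0.017 and -0.0015 on the arrays of replicate 1. The coagulation, complement, apolipoprotein and acute phase clones together had medians of -0.13, -0.12 and 0.36 on the arrays of replicate 1. Those of replicate 2 gave 0.26, 0.32 and -0.24, and those of replicate 3 gave 0.092, 0.11 and 0.049. In all, 252 of 13101 clones passed by limma, 186 higher and 66 lower. This count rested on each of the replicates, since it was 25, 18 or 42 without biological replicate 1, 2 or 3. The count was 1605 when limma took all arrays with biological replicate as a random block (847 higher and 758 lower) and 529 without background subtraction (317 higher and 212 lower), so that the excess of rises was smaller in both. In the random block fit technical arrays counted almost as separate samples, at a correlation of 0.13, which can raise the count. The number of clones passing was 165 with a loess per block of spots, 137 from the authors' log2 values and 33 against the mean of the other 3 products.

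With kerosene at 2 mg/L, no clone passed the test by limma (0 of 12605), with 2045 clones at an unadjusted p under 0.05. With all arrays and a random block limma gave 75 clones, and with a trend in the prior variance 4. Kerosene replicate 3 was a single array, while replicates 1 and 2 had 3 and 4, and each replicate had the same weight. The array with the fewest spots located, 63.3%, was array 1 of replicate 2. Without replicate 3 the limma count was 0 of 13491, with 1040 clones at an unadjusted p under 0.05. The clones with the smallest p included serum amyloid P-component at -1.48 ± 0.42 (SD, n = 3; limma adjusted p = 0.10), the 60S ribosomal protein L4-A at -0.37 ± 0.035 (limma adjusted p = 0.11) and thymosin beta-12, which binds actin, at -0.63 ± 0.15 (limma adjusted p = 0.13). Cytochrome P450IA1 stood at 0.27 ± 0.14 (limma adjusted p = 0.39), and the P450 1A3 clone that was highest with crude oil was not above background on any kerosene array and was not tested. Adjusted over the list alone, 8 of 31 acute phase clones were lower and 1 was higher, and this list was lower as a group (limma camera adjusted p = 0.0080, and adjusted p = 0.39 with an estimated correlation). Adjusted over the list alone, 10 of 158 cytoskeleton clones were lower and 1 higher (limma camera adjusted p = 0.039, and adjusted p = 0.39 with an estimated correlation). The cytochromes P450 outside family 1 were higher as a group, with 3 of 28 clones higher adjusted over the list alone (limma camera adjusted p = 0.020, and adjusted p = 0.47 with an estimated correlation). Ribosomal proteins (limma camera adjusted p = 0.015, and adjusted p = 0.67 with an estimated correlation) and iron handling (limma camera adjusted p = 0.027, and adjusted p = 0.68 with an estimated correlation) were lower as groups. So were coagulation and fibrinolysis (limma camera adjusted p = 0.036, and adjusted p = 0.74 with an estimated correlation) and complement (limma camera adjusted p = 0.043, and adjusted p = 0.67 with an estimated correlation). Skeletal muscle markers (limma camera adjusted p = 0.038, and adjusted p = 0.39 with an estimated correlation) and erythrocyte markers (limma camera adjusted p = 0.039, and adjusted p = 0.67 with an estimated correlation) were lower too. The replicates resembled each other less than those of crude oil, with a median correlation across clones of 0.27 against 0.60, and clones are not independent replicates.

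**Figure D2:**
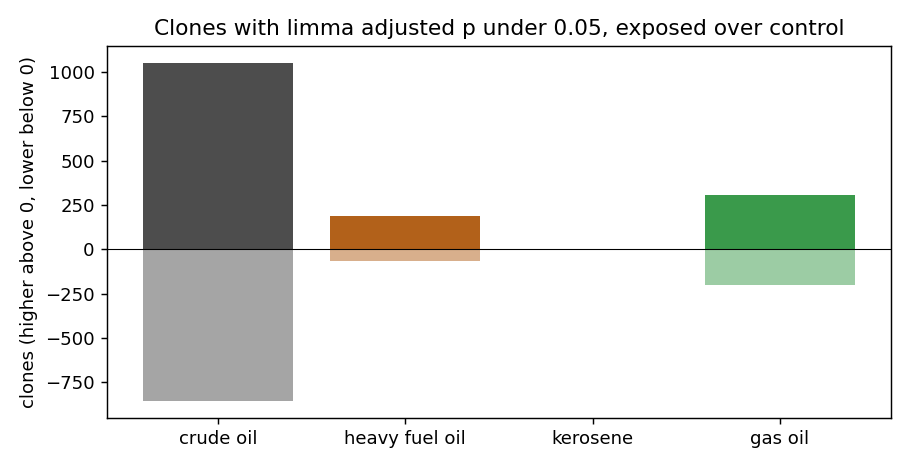
The number of clones with a limma adjusted p under 0.05 for each product (horizontal axis), higher in exposed liver above 0 and lower below 0 (vertical axis). Crude oil has 1052 higher and 855 lower, and kerosene has 0.

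Gas oil at 1 mg/L was compared with control in the same way. Clones of coagulation factor XIII B and complement factors H and B, which fell with crude oil, rose here. Coagulation factor XIII B rose by 1.92 ± 0.36 (SD, n = 3; limma adjusted p = 3.0e-04), the iron carriers serotransferrin-2 and serotransferrin-1 by 1.72 ± 0.61 and 1.56 ± 0.90, and angiogenin-2, a secreted ribonuclease, by 1.47 ± 0.51. Complement C3-1 rose by 1.37 ± 0.39, complement factor H by 1.38 ± 0.45, complement factor B by 1.31 ± 0.40 (limma adjusted p = 0.0016) and an apolipoprotein CII clone by 1.30 ± 0.52. The clones that fell most were those of stomach enzymes. An acidic mammalian chitinase clone gave -3.84 ± 0.82 (limma adjusted p = 1.9e-05), a fall of at least 8.06-fold, since its exposed signal was above background on 0 of 9 arrays. Gastricsin, a pepsin of the stomach, gave -3.11 ± 0.84 (limma adjusted p = 6.0e-05), a progastricsin clone -2.52 ± 0.74 and an intestinal mucin-like clone -1.99 ± 0.079, the last a fall of at least 1.28-fold with its exposed signal above background on 0 of 9 arrays. Of 23 clones of gastricsin, pepsin A and this chitinase, 17 fell and 0 rose. Their control signal was high on 7 of the 9 gas oil arrays, with a median log2 level between 11.64 and 12.34, against 8.86 to 9.42 on the 23 arrays of the other products. Array 2 of gas oil replicate 1 and array 3 of replicate 2 gave 9.02 and 9.01. The exposed signal lay between 8.83 and 9.42 on all 32 arrays. Hemoglobin beta, of red blood cells, changed by -1.53 ± 0.19 (limma adjusted p = 4.2e-04), and perforin, a pore-forming protein of killer lymphocytes, by -1.51 ± 0.75. Keratin 13 changed by -1.53 ± 0.099, a fall of at least 1.85-fold with its exposed signal above background on 0 of 9 arrays, while 1 other keratin 13 clone rose. The P450 1A clones gave 0.38 ± 0.30 for P450IA1 (limma adjusted p = 0.17) and 0.94 ± 1.07, 0.28 ± 0.12 and -0.033 ± 0.11 for the P450 1A3 clones, of which only the clone at 0.28 passed (limma adjusted p = 0.040).

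Of the lists, coagulation and fibrinolysis was higher with gas oil, with 17 of 44 clones higher, 0 lower and 27 not passing, or 22 higher and 0 lower adjusted over the list alone, kininogen-1 among them at 1.23 ± 0.43. The coagulation list had limma camera adjusted p = 5.9e-11, and adjusted p = 0.17 with an estimated correlation. Apolipoproteins had 19 of 57 clones higher, 0 lower and 38 not passing, or 28 higher and 0 lower adjusted over the list alone. The apolipoprotein list had limma camera adjusted p = 5.9e-11, and adjusted p = 0.17 with an estimated correlation. Complement had 13 of 56 clones higher, 0 lower and 43 not passing, or 21 higher and 1 lower adjusted over the list alone. The complement list had limma camera adjusted p = 1.4e-05, and adjusted p = 0.18 with an estimated correlation. Acute phase proteins had 3 of 32 clones higher, 3 lower and 26 not passing, or 11 higher and 4 lower adjusted over the list alone. The acute phase list had limma camera adjusted p = 0.012, and adjusted p = 0.18 with an estimated correlation. Cytochromes P450 outside family 1 had 4 of 29 clones higher, 0 lower and 25 not passing, or 6 higher and 0 lower adjusted over the list alone, with P450 2D6 at 0.52 ± 0.29 and P450 3A27 at 0.47 ± 0.14. The other P450 list had limma camera adjusted p = 4.4e-04, and adjusted p = 0.18 with an estimated correlation. Of the 6 lists of cell type markers, 3 were lower, and those of leukocytes (limma camera adjusted p = 0.40), bile duct (0.49) and egg or gonad (0.49) did not pass. Without misfit names, an alternative chosen after the data were seen, the egg or gonad list was lower (limma camera adjusted p = 0.019, against 0.38 for the full list with an estimated correlation). Erythrocyte markers had 1 of 76 clones higher, 24 lower and 51 not passing, or 2 higher and 39 lower adjusted over the list alone. The erythrocyte list had limma camera adjusted p = 7.6e-13, and adjusted p = 0.096 with an estimated correlation. Exocrine pancreas markers had 1 of 61 clones higher, 11 lower and 49 not passing, or 4 higher and 19 lower adjusted over the list alone, trypsin-1 among them at -1.24 ± 0.60. The exocrine pancreas list had limma camera adjusted p = 0.0083, and adjusted p = 0.096 with an estimated correlation. Skeletal muscle markers had 3 of 148 clones higher, 6 lower and 139 not passing, or 3 higher and 11 lower adjusted over the list alone. The skeletal muscle list had limma camera adjusted p = 0.028, and adjusted p = 0.18 with an estimated correlation. The cytoskeleton list had 0 of 174 clones higher, 10 lower and 164 not passing, or 0 higher and 15 lower adjusted over the list alone. The cytoskeleton list had limma camera adjusted p = 0.012, and adjusted p = 0.18 with an estimated correlation. In all, 506 of 13651 clones passed by limma, 305 higher and 201 lower. On the 2 arrays without a high control signal of stomach clones, the count was 198, of which 62 were among those called on all 9 arrays. Kininogen-1 at 1.09 (limma adjusted p = 0.036) and complement factor B at 0.98 (limma adjusted p = 0.050), which lay just under the limit, still passed there. Gastricsin gave 0.091 (limma adjusted p = 0.66), which follows from the choice of arrays. Those left out had a median log2 ratio of the stomach clones, gastricsin among them, more than 1 unit below 0. Several other clones named above did not pass there: factor XIII B gave 0.49 (limma adjusted p = 0.54), serotransferrin-2 0.92 (limma adjusted p = 0.075) and serotransferrin-1 0.58 (limma adjusted p = 0.35). Angiogenin-2 gave 0.28 (limma adjusted p = 0.59), complement C3-1 0.80 (limma adjusted p = 0.089), complement factor H 0.13 (limma adjusted p = 0.89) and the apolipoprotein CII clone 0.97 (limma adjusted p = 0.12). Hemoglobin beta gave -0.67 (limma adjusted p = 0.085), trypsin-1 -0.25 (limma adjusted p = 0.33), the P450 1A3 clone 0.069 (limma adjusted p = 0.64), P450 2D6 0.31 (limma adjusted p = 0.23) and P450 3A27 0.63 (limma adjusted p = 0.15), and perforin lay on the other side of 0 at 0.39 (limma adjusted p = 0.27). The lists of coagulation (limma camera adjusted p = 0.0048, and adjusted p = 0.49 with an estimated correlation), apolipoproteins (0.0071 and 0.65), complement (0.019 and 0.65), other P450 (0.0048 and 0.49) and erythrocyte markers (0.019 and 0.65) passed there by the first of these p in the same direction. Those of acute phase (0.23 and 0.73), exocrine pancreas (0.23 and 0.65), skeletal muscle (0.19 and 0.65) and cytoskeleton (0.76 and 0.86) did not pass by limma camera adjusted p. Without biological replicate 1 the count was 450 (301 higher and 149 lower), without replicate 2 it was 159 (60 higher and 99 lower) and without replicate 3 it was 92 (28 higher and 64 lower), so that most calls were lower in the last 2. With all arrays and a random block it was 1581, and from the authors' log2 values 306.

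**Figure D3:**
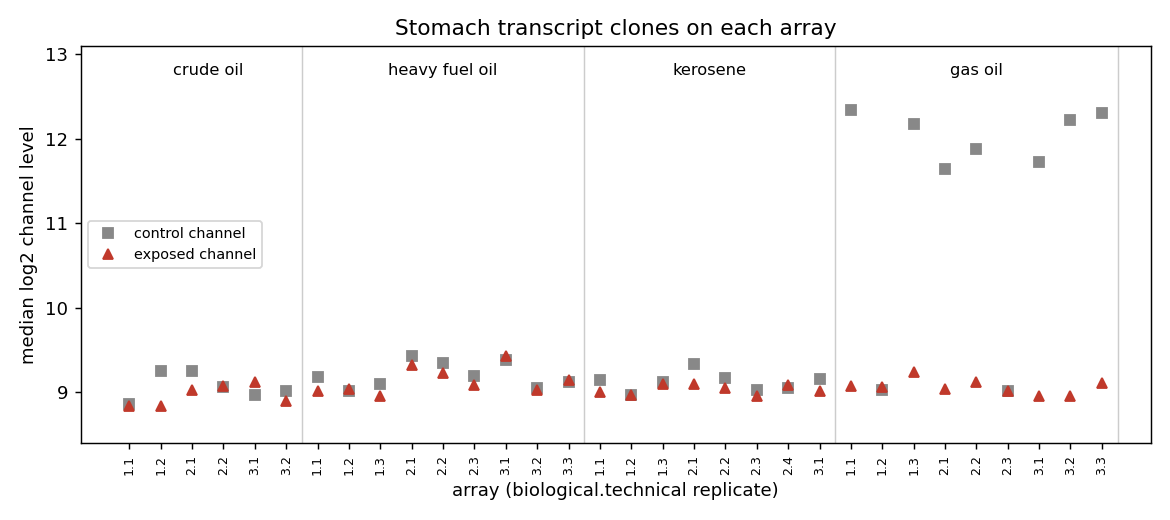
The median log2 level of 23 stomach clones (vertical axis) in the control and the exposed channel of each of the 32 arrays (horizontal axis, biological and technical replicate), by product. The control channel of 7 gas oil arrays lies between 11.64 and 12.34, and the exposed channel of every array lies between 8.83 and 9.42.

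The mean of the 4 products against control was tested over all exposures together. Over the 12 biological replicates, glutathione S-transferase P rose by 1.15 ± 0.096 (SE, n = 12; limma adjusted p = 1.9e-04), cytochrome P450IA1 by 0.94 ± 0.075 (limma adjusted p = 1.4e-04) and sulfotransferase 6B1 by 0.77 ± 0.073. These means do not hold alike for each product: glutathione S-transferase P stood at 2.84 ± 0.54 with crude oil, 1.19 ± 0.50 with heavy fuel oil, 0.48 ± 0.17 with kerosene and 0.084 ± 0.14 with gas oil (SD, n = 3 each), and both it and P450IA1 passed the limma test among products (adjusted p = 0.0037 and 0.0054). Other clones with the smallest p were an immunoglobulin heavy chain locus at 0.49 ± 0.031, the cell differentiation protein rcd1 at 0.52 ± 0.037, the Max-binding transcription factor MNT at 0.42 ± 0.034 and the lipoprotein receptor chaperone mesoderm development candidate 2 at 0.47 ± 0.041. Erythrocyte markers were lower as a group, with 6 of 72 clones higher, 32 lower and 34 not passing, or 8 higher and 32 lower adjusted over the list alone. The erythrocyte list had limma camera adjusted p = 0.014, and adjusted p = 0.42 with an estimated correlation. So were skeletal muscle markers, with 10 of 128 clones higher, 34 lower and 84 not passing, or 11 higher and 34 lower adjusted over the list alone. The skeletal muscle list had limma camera adjusted p = 0.039, and adjusted p = 0.26 with an estimated correlation. Cytochromes P450 outside family 1 were higher, with 11 of 27 clones higher, 1 lower and 15 not passing, or 12 higher and 2 lower adjusted over the list alone. The other P450 list had limma camera adjusted p = 0.039, and adjusted p = 0.42 with an estimated correlation. None of these 3 lists passed without the gas oil arrays that had a high control signal of stomach clones, where the limma camera adjusted p was 0.40, 0.11 and 0.11, and the erythrocyte list was higher, not lower, with heavy fuel oil (limma camera adjusted p = 0.036, and adjusted p = 0.72 with an estimated correlation). By limma, 4247 of 12327 clones passed, 2188 higher and 2059 lower, with a median change of 0.19 log2 units in size. Of these, 794 had the same sign in all 12 replicates. A clone-specific difference between the dyes would stand in this mean, since no array had the dyes exchanged.

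The products were compared with each other to see where their effects differed, and here a dye effect common to the arrays cancels. On all arrays, crude oil and gas oil stood furthest apart, with 409 of 13429 clones past the limma test, 114 higher with crude oil and 295 lower. Without the gas oil arrays that had a high control signal of stomach clones, and so with fewer arrays, this count was 47. That is below the 82 of crude oil minus heavy fuel oil. Crude oil minus gas oil was -3.05 ± 0.26 for coagulation factor XIII B (SE, n = 3; limma adjusted p = 6.2e-04), -2.64 ± 0.23 for complement factor B, 2.76 ± 0.27 for glutathione S-transferase P and 1.66 ± 0.21 for P450IA1 (limma adjusted p = 0.0029). It was 3.20 ± 0.30 for gastricsin. Crude oil minus kerosene passed for 2 clones of 12558, glutathione S-transferase P at 2.36 ± 0.27 (limma adjusted p = 0.022) and P450IA1 at 1.76 ± 0.21 (limma adjusted p = 0.022). Crude oil minus heavy fuel oil passed for 82 of 12995 clones, 7 higher with crude oil and 75 lower. Protein disulfide-isomerase was at -2.25 ± 0.28 (limma adjusted p = 0.022), cytoplasmic actin 1 at -1.21 ± 0.16 and beta-2-microglobulin, of the class I antigen complex, at -1.06 ± 0.15, while P450IA1 at 0.96 ± 0.21 did not pass (limma adjusted p = 0.083). This count was 2, 0 or 0 without crude oil replicate 1, 2 or 3, 0, 0 or 49 without heavy fuel oil replicate 1, 2 or 3, and 21 from the authors' log2 values. Where it was 0, between 1073 and 1558 clones had an unadjusted p under 0.05 by limma. Heavy fuel oil minus kerosene passed for 2 clones, cytoplasmic actin 1 at 1.58 ± 0.16 (limma adjusted p = 0.0080) and an elongation factor 1-alpha at 0.93 ± 0.12 (limma adjusted p = 0.049). Heavy fuel oil minus gas oil passed for 107 clones, with hemoglobin beta-1 at 1.85 ± 0.16 and actin 1 at 2.09 ± 0.16 (limma adjusted p = 4.3e-04). Kerosene minus gas oil passed for 98, with factor XIII B at -2.75 ± 0.26 and gastricsin at 2.87 ± 0.30 (limma adjusted p = 0.0036). With 1 replicate left out, the count for crude oil minus kerosene ran from 0 to 4, for heavy fuel oil minus kerosene from 0 to 1, for crude oil minus gas oil from 139 to 452, for heavy fuel oil minus gas oil from 48 to 114 and for kerosene minus gas oil from 21 to 176. Without the 7 gas oil arrays that had a high control signal of stomach clones, the counts against crude oil, heavy fuel oil and kerosene were 47, 0 and 0, the last of these with 1438 and the one before with 1536 clones at an unadjusted p under 0.05 by limma. Crude oil minus gas oil was then -1.63 (limma adjusted p = 0.24) for factor XIII B, no longer passing, and -2.31 (limma adjusted p = 0.025) for complement factor B, 2.16 (limma adjusted p = 0.036) for glutathione S-transferase P and 1.82 (limma adjusted p = 0.025) for P450IA1, which passed, while gastricsin was at -0.0071 (limma adjusted p = 0.99). The arrays were left out by the ratio of the stomach clones, so the value of gastricsin follows from that choice.

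The test for any difference among the 4 products passed for 259 of 12327 clones by limma. It included P450IA1 (limma adjusted p = 0.0054), glutathione S-transferase P (0.0037), coagulation factor XIII B (0.0014), complement factor B (0.0022), hemoglobin beta-1 (0.0022), serum amyloid P-component (0.0037) and cytoplasmic actin 1 (0.0014). The mean log2 ratio of P450IA1 was 2.04 ± 0.23 with crude oil, 1.07 ± 0.43 with heavy fuel oil, 0.27 ± 0.14 with kerosene and 0.38 ± 0.30 with gas oil (SD, n = 3 each). Serum amyloid P-component stood at -2.17 ± 0.62, -0.73 ± 0.24, -1.48 ± 0.42 and 0.81 ± 0.31 in the same order. Crude oil and heavy fuel oil shared 65 higher and 24 lower clones, where 14.6 and 4.22 would be shared if the calls were independent, and 16 clones went opposite ways, where 17.1 would. Crude oil and gas oil shared 65 higher and 31 lower clones, where 23.5 and 11.9 would be, and 66 went opposite ways, where 33.8 would. A dye effect common to the arrays would add to the clones shared in 1 direction. Without the gas oil arrays that had a high control signal of stomach clones, the test among the products passed for 33 clones.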

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

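The tests of the stomach clones, of stomach tissue diluting the control RNA, and the refit without the gas oil arrays concerned were chosen after the result was seen. Differences between the products drew attention because the test of the difference itself passed. Crude oil minus gas oil passed for 409 clones, crude oil minus heavy fuel oil for 82, and crude oil minus kerosene for 2. Heavy fuel oil minus kerosene passed for 2, heavy fuel oil minus gas oil for 107 and kerosene minus gas oil for 98. For each of these pairs, 1 of the 10 splits of 6 replicates, the real one, gave as many clones, and the highest of the others gave 0; 10 splits are too few for a share under 0.05. The F test among the 4 products passed for 259 clones, and among 100 groupings drawn 1 gave as many, the real one, against 38 in the highest of the others. This share is the smallest these draws could give, and it makes chance an unlikely source of the count on all arrays. Gas oil was given at 1 mg/L and the others at 2 mg/L, so its dose stays among the untested explanations. Stomach transcripts in the control channel also set gas oil arrays apart, and could by themselves favour the real grouping. Without those arrays the F test passed for 33 clones. The groupings were not drawn again there, so chance was not tested for that count. Of 12 checks of array measures for a single array far from its group, 0 found one.

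For the counts against control, the signs of the replicates were turned in all possible ways, mirror images counted once. The real signs gave 1907 clones for crude oil, 252 for heavy fuel oil and 506 for gas oil, each in 1 of 4 patterns, with 0 as the highest of the others. Kerosene gave 0 by limma in all 4, with 2045 clones at an unadjusted p under 0.05 and 75 by limma with all arrays. These patterns are too few for a share under 0.05. For the mean of the products, the real signs gave 4247 clones, the highest of the 100 patterns drawn, the real one being 1 of them, with 3137 for the next. The replicates thus shared their direction more than randomly drawn signs did, at 1 of 100, the smallest share these draws could give. A dye effect common to all arrays would also favour the real signs, here and for each product. These counts therefore do not separate exposure from dye.

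Stomach transcripts were lower in exposed than in control liver on 7 of 9 gas oil arrays. Against a lowering by gas oil, the exposed channel stood 0.032 log2 units above that of the other products (median of 23 clones), while the control channel stood 1.64 above, up to 4.28 for a chitinase clone. A candidate explanation is therefore stomach tissue, or RNA from it, in the control RNA of those arrays; none of these clones is in a list fixed beforehand (0), and 18 were also above background on most arrays of the other products. Since arrays of the same biological replicate differ, technical arrays of 1 replicate may not share their control RNA. No biological explanation was tested beyond the product itself, and the labels name no tissue but liver.

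The median of the 178 coagulation, complement, apolipoprotein and acute phase clones was below 0 in each crude oil replicate (-0.35, -0.19 and -0.31) and above 0 in each gas oil replicate (0.17, 0.34 and 0.46), though most of these clones did not pass on their own and no list passed with an estimated correlation (smallest limma camera adjusted p 0.21 with crude oil and 0.17 with gas oil). The choice of background correction or of normalization method is unlikely as its source, since the smallest difference among the 3 alternatives was 0.92 of the main one. These were no background subtraction, print-tip loess and the authors' values. All 3 were normalized within arrays, so an effect of normalization itself could not show. Stomach RNA diluting the control of the gas oil arrays cannot be the whole of it, because each crude oil replicate was below 0, the highest at -0.19. On the 2 gas oil arrays without stomach signal these clones had a median of 0.33 and 0.020, so whether the rise with gas oil stays without that signal rests on 1 array; the lists of coagulation, complement and apolipoproteins passed there by limma camera adjusted p (0.0048, 0.019 and 0.0071) but not with an estimated correlation (0.49, 0.65 and 0.65), and acute phase by neither (0.23 and 0.73). Different control RNA between the products stays open, with 41.4% of the difference in the control channel. An effect of the product or its dose on liver secretion genes stays open as well, untested.

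The mean of the 4 products differed from control for more clones than any single product. A dye effect would be the same on every array and could produce such a mean, in which case the clones called should differ among products no more often than the rest and keep 1 sign in all 12 replicates. They passed the F test 1.12 times as often as the others, 2.26% against 2.02%, which does not settle it, and 18.7% had the same sign in all 12 replicates. A shared effect of hydrocarbons cannot be told apart from it, since no array had the dyes exchanged.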

How the results depend on the processing

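The test against the other 3 products, the refits without the arrays of few located spots and without the gas oil arrays with stomach transcripts, the lists without misfit names and the pre-ranked camera were chosen after the data were seen. Counts not named here stayed within 1.5 times of those reported; in all 114 counts under an alternative did and 39 did not, besides the replicates left out. Of the named clones' values, 3377 kept their side of the limit, 365 no longer passed and 79 passed anew. Of the lists' values, 1932 kept their side, 40 no longer passed and 23 passed anew. Direction was compared only for values that passed before or under the alternative, and it turned for 15 of the named clones' values. Values that passed in neither may have changed direction. Except where stated, the cause was not tested. With all arrays and duplicateCorrelation, the limma counts were 743 for crude oil minus gas oil (from 409), 14 for crude oil minus kerosene (from 2), 723 for the F test (from 259), 1581 for gas oil vs control (from 506), 658 for heavy fuel oil minus gas oil (from 107), 0 for heavy fuel oil minus kerosene (from 2), 1605 for heavy fuel oil vs control (from 252), 287 for kerosene minus gas oil (from 98) and 75 for kerosene vs control (from 0). From the authors' log2 values they were 228 for crude oil minus gas oil (from 409), 21 for crude oil minus heavy fuel oil (from 82), 0 for crude oil minus kerosene (from 2), 1139 for crude oil vs control (from 1907), 144 for the F test (from 259), 306 for gas oil vs control (from 506) and 137 for heavy fuel oil vs control (from 252). The 0 there for crude oil minus kerosene came with 1005 clones at an unadjusted p under 0.05. Without the arrays of few located spots they were 21 for crude oil minus heavy fuel oil (from 82) and 0 for heavy fuel oil minus kerosene (from 2). Without background subtraction the count was 529 for heavy fuel oil vs control (from 252), with print-tip loess 0 for heavy fuel oil minus kerosene (from 2) and 165 for heavy fuel oil vs control (from 252), with all flag codes kept 4 for crude oil minus kerosene (from 2), without the filter 1 for heavy fuel oil minus kerosene (from 2), and with an intensity trend 161 for kerosene minus gas oil (from 98) and 4 for kerosene vs control (from 0). Heavy fuel oil minus kerosene had 1085, 856 and 698 clones at an unadjusted p under 0.05 where its limma count was 0 with duplicateCorrelation, print-tip loess and the arrays of few located spots left out.

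With the replicate number as a block, the count was 1165 for crude oil vs control (from 1907); only 1 of 18 pairs of replicates with the same number correlated above 0.1, so the numbers do not pair the samples. Against the mean of the other 3 products, the counts were 80 for crude oil vs control (from 1907) and 33 for heavy fuel oil vs control (from 252), and cytochrome P450IA1 with gas oil was -0.75, the opposite of its ratio to control, since it was higher with crude oil and heavy fuel oil. Without the gas oil arrays with stomach transcripts, which leaves 2 arrays of 2 replicates, the counts were 47 for crude oil minus gas oil (from 409), 33 for the F test (from 259), 198 for gas oil vs control (from 506), 0 for heavy fuel oil minus gas oil (from 107) and 0 for kerosene minus gas oil (from 98); fewer arrays and the loss of the stomach signal both act here. Values that then lay on the other side of 0 for gas oil were the 40S ribosomal protein S20 at 0.037, cardiac actin at 0.13, collagen alpha-3(VI) at 0.32, gastricsin at 0.091, histone H2AV at 0.050, histone H3.3 at -0.12, a calsequestrin-like clone at 0.26, perforin at 0.39, proteasome alpha 7 at -0.088 and the differentially regulated trout protein 1 at 0.44. Gastricsin in crude oil, heavy fuel oil and kerosene minus gas oil was then -0.0071, -0.089 and -0.33, and progastricsin in kerosene minus gas oil -0.033. None of these passed. The arrays were left out by the ratio of the stomach clones, so the loss of the gastricsin and progastricsin differences follows from that choice.

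The total of list calls by camera over the products was 30, and 19 without the arrays of few located spots, which were of heavy fuel oil and kerosene. That of cell type markers was 7, and 4 without those arrays and 4 with the authors' values. The total of named clones past the limit was 209, and 79 against the other 3 products, 139 with the authors' values and 119 without the gas oil arrays with stomach transcripts. These are totals, so a call under an alternative need not be among those reported. Leaving out each biological replicate in turn, the counts ran from 100 to 616 for crude oil, 18 to 42 for heavy fuel oil, 92 to 450 for gas oil, 0 to 0 for kerosene, 3281 to 4063 for the mean and 116 to 417 for the F test. For crude oil minus heavy fuel oil they ran from 0 to 49, minus kerosene 0 to 4 and minus gas oil 139 to 452; for heavy fuel oil minus kerosene 0 to 1 and minus gas oil 48 to 114; for kerosene minus gas oil 21 to 176. Lists ran from 24 to 32, cell type markers from 5 to 7 and named clones from 147 to 208. Signal near background limits clones such as the P450 1A3 clone, whose control signal allows only a bound.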

Other observations

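The comparison of each product with the mean of the other 3, in which a common dye effect cancels, was chosen after the data were seen. Crude oil then had higher metallothionein clones (3 of 6 clones higher and 0 lower, or 4 and 0 adjusted over the list alone, limma camera adjusted p = 7.5e-07, and adjusted p = 0.13 with an estimated correlation) and higher aryl hydrocarbon receptor genes (1 of 16 clones higher and 0 lower, or 2 and 0 adjusted over the list alone, limma camera adjusted p = 0.048, and adjusted p = 0.13 with an estimated correlation). Heavy fuel oil had higher translation factors (6 of 174 clones higher and 0 lower, or 15 and 0 adjusted over the list alone, limma camera adjusted p = 0.0040, and adjusted p = 0.26 with an estimated correlation), with elongation factor 1-alpha 1 at 1.09 ± 0.33 and elongation factor 2 at 0.74 ± 0.034 against control (SD, n = 3). Ribosomal proteins were higher as well (6 of 492 clones higher and 0 lower, or 15 and 0 adjusted over the list alone, limma camera adjusted p = 9.3e-10, and adjusted p = 0.26 with an estimated correlation), and so were erythrocyte markers (4 of 72 clones higher and 0 lower, or 23 and 1 adjusted over the list alone, limma camera adjusted p = 4.6e-13, and adjusted p = 0.097 with an estimated correlation). Cytoskeleton genes were also higher (3 of 151 clones higher and 0 lower, or 11 and 0 adjusted over the list alone, limma camera adjusted p = 0.012, and adjusted p = 0.26 with an estimated correlation), as were skeletal muscle markers (1 of 128 clones higher and 0 lower, or 2 and 0 adjusted over the list alone, limma camera adjusted p = 0.018, and adjusted p = 0.26 with an estimated correlation) and egg or gonad markers (3 of 55 clones higher and 0 lower, or 7 and 0 adjusted over the list alone, limma camera adjusted p = 0.012, and adjusted p = 0.097 with an estimated correlation). Without misfit names, neither skeletal muscle (limma camera adjusted p = 0.12) nor egg or gonad markers (0.46) passed. Against control, only ribosomal proteins and erythrocyte markers among these lists were higher with heavy fuel oil by limma camera adjusted p. The erythrocyte, cytoskeleton and skeletal muscle lists were lower against control with gas oil and with kerosene. Their difference here therefore lay in part in the products that heavy fuel oil was set against. Iron handling clones were lower with kerosene as a group, though none passed singly (0 of 67 clones higher and 0 lower, or 0 and 0 adjusted over the list alone, limma camera adjusted p = 3.0e-07, and adjusted p = 0.31 with an estimated correlation). In gas oil, complement was higher (16 of 50 clones higher and 0 lower, or 20 and 0 adjusted over the list alone, limma camera adjusted p = 4.6e-11, and adjusted p = 0.075 with an estimated correlation). These are a selection, since by limma camera adjusted p 8 of the 35 lists passed for crude oil, 10 for heavy fuel oil, 6 for kerosene and 5 for gas oil. The gas oil arrays with stomach transcripts in the control channel were kept in all of these comparisons, which were not repeated without them.

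Several further genes passed against control. Ferritin middle subunit, which stores iron, rose with crude oil by 1.00 ± 0.45 (SD, n = 3; limma adjusted p = 0.0036), with 13 of its 22 clones passing higher and 0 lower. The iron handling list that holds it did not pass with crude oil (limma camera adjusted p = 0.65, and adjusted p = 0.85 with an estimated correlation), with 15 of 70 clones higher, 4 lower and 51 not passing, or 19 higher and 9 lower adjusted over the list alone. Mucin-like protein 1 rose with crude oil by 0.77 ± 0.17 (limma adjusted p = 0.0021), and 24-dehydrocholesterol reductase, of cholesterol synthesis, gave -0.92 ± 0.26 (limma adjusted p = 0.0092). A histone H3.3 clone gave -1.07 ± 0.33 with crude oil and 1.04 ± 0.37 with gas oil, but -0.12 (limma adjusted p = 0.84) for gas oil without the arrays with stomach transcripts. Fatty acid-binding protein of the heart type had clones on both sides with crude oil, 3 lower and 2 higher. Selenoprotein Pa, a selenium carrier of plasma, rose with heavy fuel oil by 1.07 ± 0.64 (limma adjusted p = 0.030), and cytochrome P450 3A27 by 1.00 ± 0.12 (limma adjusted p = 0.042). Calreticulin, a chaperone of the endoplasmic reticulum, rose with gas oil by 0.80 ± 0.25 and protein disulfide-isomerase by 1.14 ± 0.64, the latter a gene of which another clone fell with crude oil. Without the arrays with stomach transcripts these gave 0.83 (limma adjusted p = 0.050), just over the limit, and 0.73 (limma adjusted p = 0.10), and did not pass. The oestrogen response list, which holds egg envelope proteins, had 1 of 20 clones higher, 2 lower and 17 not passing, or 1 higher and 3 lower adjusted over the list alone with crude oil (limma camera adjusted p = 0.76, and adjusted p = 0.82 with an estimated correlation).

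Technical arrays of the same biological replicate correlated across 8899 clones with a median r of 0.36, and arrays of different biological replicates of a product with 0.28, where clones are not independent replicates. For kerosene the values were 0.081 and 0.20. The erythrocyte list had a median log2 ratio of -0.15 and -0.10 on the gas oil arrays without stomach signal, and between -0.60 and -0.22 on the others.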
